A study of Mus musculus with 3 samples.

How the data were processed

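Single-cell RNA-seq was made from bone marrow of wild-type C57BL6 mice aged 10 to 11 weeks, per the labels. Per the labels' protocols, marrow was depleted of lineage-positive cells and 3 populations were sorted, with 1 sample each: common lymphoid progenitors, Fraction A cells and pro-B cells. Libraries followed the Chromium 3' protocol of 10x Genomics, in which each captured RNA molecule carries a unique molecular identifier (UMI). Per the submitters' processing notes, reads were processed with Cell Ranger 1.3 and the mouse build mm10 (GRCm38), and Seurat 2.1 was used. The series design text instead names Seurat 1.4.

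The authors deposited 1 table of raw counts (UMIs per gene and cell, not normalized) with 14106 genes and 3326 cell barcodes. Barcodes carry a suffix of 1, 2 or 3, and no label says which sorted sample a suffix stands for. Cells were therefore given to no sample, the table was treated as 1 pooled sample, and none of the planned comparisons between the sorted populations, or of a cell class between them, was made. The suffix was used only to recompute values within sets of barcodes. Every gene in the table had a count in at least 3 cells, and the table held 0 immunoglobulin segment or constant genes. Of the gene symbols, 13651 matched the symbol table of the reference annotation.

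Cells with at least 500 detected genes and at most 10% mitochondrial counts were kept, which left 3307 cells with 28268208 UMIs. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used (scanpy 1.11.5, igraph 0.11.9). The plan had been to cluster each sorted library alone on all variable genes. The reported clustering instead used all cells together and kept the fixed gene lists out of the features, so that list genes could be compared between clusters. It was chosen after clusters from several settings had been seen, and 10 other clusterings are given beside it. Markers of each cell type and the gene lists were fixed before the data were examined, but the rule that turns markers into names was set afterwards. Under it a cluster took the name of a marker set with a mean log2 fold of at least 0.5 over all other cells (10 CPM added to both sides), at least 3 detected markers at least 1.5-fold higher, and no other set with more markers among its 10 leading genes. Markers counted as detected in at least 10% of a cluster's cells. Leading genes had a UMI in at least 25% of cells and at least 50 CPM. A cluster took no name if its median UMIs lay below the median of all cells divided by 3 and no marker of its set was a leading gene. Sets for pro-B, pre-B and immature or mature B cells shared the name B-lineage-like. Scrublet, as run in scanpy within each suffix set, marked 19 cells (0.575%) as doublets; they were kept in the reported values.

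For 4 comparisons between clusters, chosen after the clusters and their leading genes were known, UMIs were summed per cluster and given as counts scaled to 1000000 (CPM). Ratios carry exact 95% conditional Clopper-Pearson intervals. Each list's median log2 ratio used members with at least 10 summed counts, with counts under 3 set to 3, and was ranked among 10000 random lists of its size matched on mean CPM in 20 bins. Its range came from 200 redraws of the counts. The rule for named genes took the 10 highest and 10 lowest log2 ratios among genes of at least 100 CPM in the higher cluster, leaving out clustering features (a limit added after the data were seen), and the 2 highest and 2 lowest members of each list. The comparisons with cluster 2 were repeated against clusters 2, 3 and 4 together, chosen after the unnamed clusters' genes were seen. Ebf1 in the comparisons of B-lineage-like clusters and Cd79a in that of pDC-like clusters fall outside the rule and were added after their values were seen. Some list genes also lead a cluster or served as naming markers, so medians were recomputed without them. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs, which left out 45 shallower cells. With 1 pooled sample there are no replicates: no p-value is given, and all intervals cover counting error only. Cluster similarity was Spearman's correlation across genes of at least 50 CPM. This measure had been planned between clusters of different libraries and was run between clusters of the pooled table. A version centred on the mean over clusters had been computed first. Ratio intervals, list ranks and thinning were tested on simulated data: over 9838 simulated genes the interval held the true value for 96.3% of unchanged genes, and genes simulated 2-fold higher had a median log2 ratio of 0.98.

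Alternatives were TMM factors (edgeR 4.0.16), size factors (DESeq2 1.42.0), equal weight per cell, totals without mitochondrial and ribosomal protein genes, other cell filters, removal of doublet calls, other count minimums, other clusterings, other thinning depths and single suffix sets. Libraries without their non-lymphoid clusters had also been intended and were not compared, for want of a map from cells to libraries. Gene positions came from GENCODE M21 on GRCm38. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, matplotlib 3.10.9 and R 4.3.3 were used.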

Results

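The transcriptomes of 3307 bone marrow cells from sorted lymphoid progenitor compartments were analysed. The series asked which cells these compartments hold on the way to B lymphocytes. Labels describe 3 sorted samples, 1 per population, but the deposited count table does not tie a cell to its sample. Values below therefore describe cell clusters in the pooled table and not the sorted populations. The kept cells held a median of 7962 UMIs and 2593 detected genes, with 2.96% mitochondrial counts. Their total was 28268208 UMIs. Depth differed between barcode suffix sets, with a median of 10246 UMIs and a total of 19988359 in the 1801 cells of suffix 1, 7739 and 2680719 in the 313 cells of suffix 2, and 2932 and 5599130 in the 1193 cells of suffix 3. There were no replicates, and all intervals cover counting error only.

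Clustering gave 13 clusters, of which 5 were B-lineage-like, 1 progenitor-like, 2 like plasmacytoid dendritic cells (pDC-like) and 1 granulocyte-like, while 4 stayed unnamed. B-lineage-like clusters held 44.5% of cells (95% exact interval 42.8 to 46.2). The progenitor-like cluster 2, in which 7 of 9 detected progenitor markers were at least 1.5-fold higher than in other cells, held 14.1% (13 to 15.4). The pDC-like clusters 9 and 10, with Siglech among their leading genes, held 9.83% (8.83 to 10.9), and the granulocyte-like cluster 13, led by the neutrophil protease gene Elane, held 3.42% (2.82 to 4.09). Per the labels, the sorts excluded cells with the myeloid and dendritic surface proteins Gr1, Mac1 and CD11c. Another 28.2% of cells were in unnamed clusters. These shares depended on the clustering. Over 11 clusterings the B-lineage-like share ran from 26.4% to 44.7%, the progenitor-like share from 0% to 31.2%, the pDC-like share from 6.89% to 17.4% and the granulocyte-like share from 1.03% to 6.05%. With each suffix set clustered alone on all variable genes, the nearest to the planned design, they were 29.4%, 0%, 14.7% and 1.66%. Names there were scored against the other cells of the same suffix set, which can lower the score of markers those cells share. In suffix 1, 273 cells in a cluster led by Rtp4, Irf7 and Gm5111, which also lead cluster 2, took the name plasma cell. In suffix 3, 61 cells took the name T cell. The 0% therefore does not show that progenitor-like cells were absent.

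**Figure D1:**
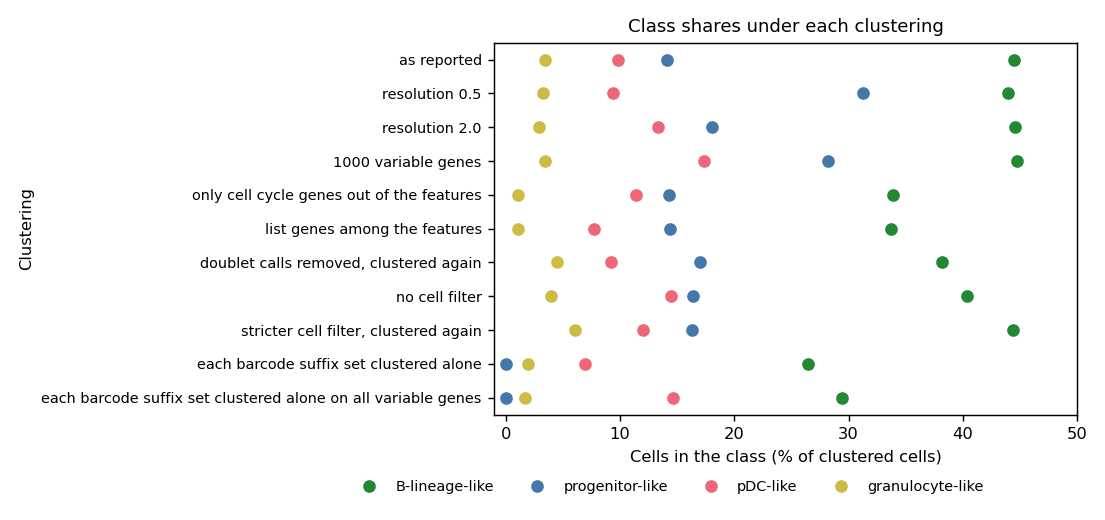
Share of cells in each named class (x axis, percent of clustered cells) under the reported clustering and 10 others (y axis), 1 point per class and clustering. The B-lineage-like share lies between 26.4% and 44.7%, and no cluster is named progenitor-like where suffix sets are clustered alone. Names there are scored within each suffix set, so this does not show that such cells are absent.

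The B-lineage-like cluster 7 was set against the progenitor-like cluster 2. Of 467 cluster 2 cells 455 had suffix 1, and of 195 cluster 7 cells 147 had suffix 2. Values over all cells thus largely compare 1 suffix set with another. Components of the pre-B cell receptor (pre-BCR), the signalling complex of B-cell precursors, and of the B cell receptor (BCR) form 1 list, which was higher in cluster 7: it had a median log2 ratio of 2.59 (range over redrawn counts 1.59 to 2.76), and 9 of 15 measured members were at least 2-fold higher. The median lay at percentile 100 of random lists. The surrogate light chain gene Igll1 was at 317 CPM against 1.03 CPM (log2 ratio 8.27, interval 6.91 to 10.15), and Cd79a at 737 CPM against 37.7 CPM (4.29, 4.04 to 4.55). In the B-lineage transcription factor list 5 of 14 members were at least 2-fold higher, with a median of 0.29. Ebf1 and Pax5, which set up and maintain B-lineage identity, had log2 ratios of 2.03 (1.93 to 2.13) and 4.03 (3.37 to 4.76). Against cluster 2 alone, S-phase and G2/M-phase genes had medians of 1.48 and 2.19. The unnamed clusters 3 and 4, which include dividing cells, also held progenitor transcripts, however. Without thinning, Flt3, Cd34 and Dntt were found in 92.3%, 86.0% and 98.6% of cluster 3 and 96.9%, 88.1% and 97.9% of cluster 4. In the granulocyte-like cluster they were in 59.3%, 85.0% and 51.3%, so Cd34 does not set clusters 3 and 4 apart. These clusters scored 0.46 and 0.09 for progenitor markers, under the 0.5 needed for a name. Against clusters 2, 3 and 4 together, the S-phase median was 0.20 and the G2/M-phase median -0.71, so no direction of cell division genes is drawn. Members of the multipotent and stem-cell list were lower, at a median of -1.29 with 10 of 15 at least 2-fold lower, among them Cd34 at -3.55. Against clusters 2, 3 and 4 together this median was -0.91, and the pre-BCR and BCR median 3.03. Without leading genes and naming markers, which include the sort gate genes Flt3, Kit and Ly6a, the multipotent median against cluster 2 was -1.39. Of 8 members 6 were then at least 2-fold lower. Dissociation and immediate-early genes, a list of genes that also respond to the handling of cells, were lower too, at -1.47, which was -0.996 within suffix 1 and -0.67 within suffix 2, with Egr1 at -4.17. Igll1, Cd79a, Ebf1, Pax5 and Cd34 are among the markers that named the clusters, and without naming markers and leading genes the pre-BCR and BCR median was 0.38, with 0 of 6 members at least 2-fold higher and at percentile 96.6 of random lists. The transcription factor median was then 0.11, with 2 of 8 at least 2-fold higher and at percentile 52.3, so no direction is drawn from that list. With only leading genes left out, the pre-BCR and BCR median was 1.97, with 8 of 14 members at least 2-fold higher and at percentile 100. The pre-BCR and BCR result thus rests largely on the naming markers. Within suffix 1 the pre-BCR and BCR list had a median of 1.29 and within suffix 2, with 12 progenitor-like cells, 0.42. Both lie under the range over all cells. The multipotent median was -0.43 and -1.03, and the transcription factor median 0.44 and -0.03. Within suffix 2 Igll1, Cd79a, Ebf1 and Pax5 had log2 ratios of 3.71, 2.48, 1.06 and 1.64. That of Igll1 (2.44 to 7.35) rests on 2 progenitor-like counts, set to 3 for the ratio, and that of Pax5 (0.062 to 3.94) on 3.

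Cluster 6, which Vpreb1, Igll1 and Lef1 lead, was set against cluster 7. Of 200 cluster 6 cells 172 had suffix 3, and of 195 cluster 7 cells 147 had suffix 2. Values over all cells thus largely compare 1 suffix set with another here too, and those within suffix 2 rest on 28 cluster 6 cells. G2/M-phase genes were higher in cluster 6, at a median log2 ratio of 1.49 (1.35 to 1.61) with 36 of 50 at least 2-fold higher, and at 1.59 within suffix 2, the only set with enough cells of both. The B-cell coreceptor Cd19 had a ratio of 4.49 (3.69 to 5.42) and Ebf1 of 1.06 (0.99 to 1.14). The cytokine receptor Flt3 was lower, at 5.14 CPM against 280.7 CPM (-5.77, -6.91 to -4.83). So were the multipotent list, at -1.96 (-1.25 within suffix 2) with 10 of 11 members at least 2-fold lower, and the MHC class II list, which serves antigen presentation, at -1.72 with 6 of 9. Within suffix 2 the MHC class II median was -1.38. Without leading genes and naming markers, which include the sort gate genes Flt3, Kit and Ly6a, 4 of 5 multipotent members were at least 2-fold lower. Their median was -1.96. Dissociation and immediate-early genes had a median of -1.43 (-1.18 within suffix 2), with Fos at -5.57. Ly6d, which encodes a surface protein used to divide lymphoid progenitors, was at 162 CPM against 3598 CPM (-4.47, -4.65 to -4.30). Within suffix 2 Cd19, Flt3, Fos and Ly6d had ratios of 3.49, -4.10, -2.45 and -3.18. Cd19 and Flt3 are genes of the sort gates. The sort itself can set part of their ratios over all cells, so these are read as a check of it. The pre-BCR and BCR list had a median of 0.61, which was 0.03 within suffix 2 and -0.34 without leading genes and naming markers (Cd19, Ebf1 and Flt3 are such markers), so no direction is drawn from it. The transcription factor list likewise had 0.62 for all cells, -0.08 within suffix 2 and -0.49 without those genes, and clustering at resolution 0.5 gave 0.08 for MHC class II and 0.96 for G2/M-phase genes.

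Cluster 1, led by Slfn2 and Cd74, was set against cluster 6. It held 663 cells with a median of 2375 UMIs, against 5157 in cluster 6. Cell division genes were lower: 46 of 50 G2/M-phase genes and 40 of 43 S-phase genes were at least 2-fold lower, with medians of -3.21 (-3.27 to -2.86) and -2.89. Dividing B-lineage-like cells were clustered apart, however: a UMI of Mki67, Top2a, Cdk1 or Ccnb2 was found in 100% of thinned cluster 5 and 81.1% of cluster 11. Dntt was found in 1.48% and 2.10% of these, against 1.45% of cluster 1. The medians therefore describe cluster 1 as clustered, and no wider direction of cell division genes is drawn. The G2/M-phase median was -3.42 within suffix 3 and -0.94 within suffix 2, which held 16 cluster 1 cells, and the S-phase median -3.25 and -0.72. Ribosome biogenesis genes and Myc targets had a median of -1.94, with 14 of 16 members at least 2-fold lower, and -1.33 within suffix 2. Dntt, which adds nucleotides at V(D)J joins, was at 10.6 CPM against 1028 CPM (-6.60, -7.36 to -5.94). The MHC class II list had a median of 1.16 with 6 of 9 members at least 2-fold higher, but without naming markers and leading genes such as Cd74 it was 0.81, with 2 of 5 members, at percentile 92.0 of random lists, so no direction is drawn from it. Its member H2-Aa, a naming marker, was at 166 CPM against 13.7 CPM (3.60). Dissociation and immediate-early genes had a median of 1.79 (2.69 within suffix 2), with Klf2 at 4.90, and mitochondrially encoded genes one of 0.56. Ly6d was higher, at 3034 CPM (4.23, 4.05 to 4.40), and Ebf1 at 0.93 (0.88 to 0.98). Within suffix 2 Dntt, H2-Aa and Ly6d had ratios of -3.93, 2.24 and 1.95. That of Dntt (-6.21 to -2.37) rests on 3 cluster 1 counts and that of H2-Aa on 4 and 6 counts. Within suffix 3 Ly6d had a ratio of 4.92.

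The pDC-like clusters were set against cluster 2. Cell division genes were higher in the pDC-like cells than in this largely non-dividing cluster, with G2/M-phase and S-phase medians of 3.95 (3.66 to 4.27) and 2.18. Against clusters 2, 3 and 4 together, which include dividing cells, these were 0.97 and 0.91, with 23 of 50 and 16 of 43 genes at least 2-fold higher. Against cluster 2 the G2/M-phase median was 3.84 within suffix 1 and 1.98 within suffix 2, and the S-phase median 2.21 and 1.28. Multipotent genes were lower, at -1.86 with 11 of 15 members at least 2-fold lower, and so were members of the IL-7 receptor and STAT5 list, at -1.07. Against clusters 2, 3 and 4 together these were -1.34 and -0.92. Without leading genes and naming markers, which include the sort gate genes Flt3, Kit, Ly6a and Il7r, the medians against cluster 2 were -2.03 and -1.18. Ebf1 was at 45.6 CPM against 323 CPM (-2.83, -3.10 to -2.56), and Rag1, needed for V(D)J recombination, at -3.69 (-4.66 to -2.85). Against the 3 clusters together these ratios were -1.83 and -2.60, within suffix 1 -4.96 and -5.43, the latter on 3 pDC-like counts, and within suffix 2 -1.47 and -1.55, the latter with an interval that spans 0. Ly6d was higher, at 4970 CPM (2.20, 2.15 to 2.25), with an interval of 1.35 to 1.65 within suffix 2. Cd79a had a ratio of 0.85 over all cells but -4.37 within suffix 1 and 1.51 within suffix 2. The MHC class II and interferon lists likewise had opposite signs in suffixes 1 and 2, at -1.32 and 1.07 and at -1.05 and 0.67, while the multipotent median was -1.91 and -0.81.

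**Figure D2:**
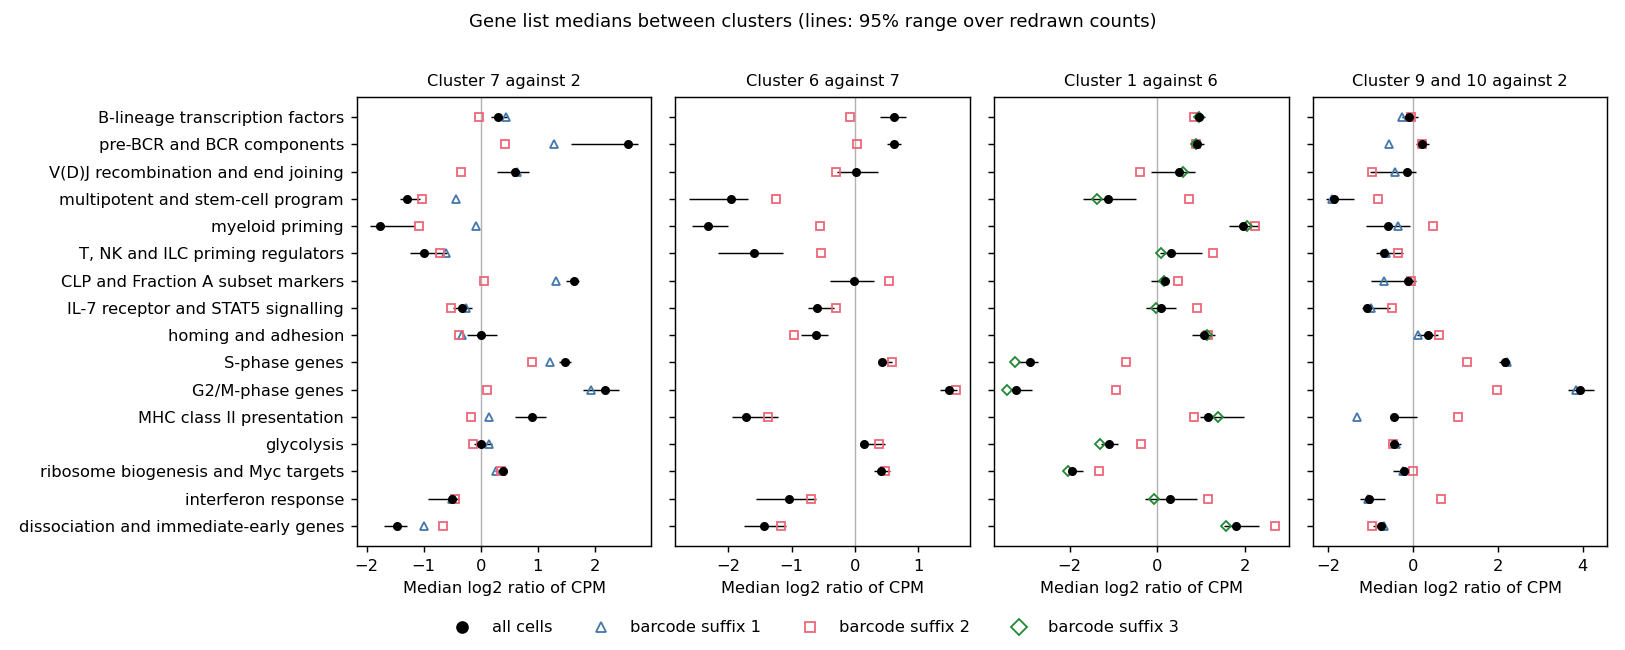
Median log2 ratio of CPM (x axis) of each fixed gene list (y axis) in the 4 cluster comparisons, over all cells with the 95% range over redrawn counts, and within each barcode suffix set with at least 10 cells on both sides. Over all cells, S-phase and G2/M-phase genes have medians above 0 in every comparison except cluster 1 against 6, where they lie at -2.89 and -3.21; cluster 2 lacks the dividing cells of clusters 3 and 4.

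At an equal depth of 2000 UMIs, Ebf1 was detected in 35.5% (31.2 to 40.1) of the 467 progenitor-like cells, 83.5% (77.5 to 88.4) of cluster 7 and 97.0% (93.5 to 98.9) of cluster 6. In the granulocyte-like cells, which should lack it, it was found in 0 of 113, which allows a share of cells with a UMI of up to 2.65% at 3 cells (exact upper bound 3.21%). Median depths before thinning were 8328 UMIs in cluster 2 and 16578 in the granulocyte-like cluster. Without thinning the Ebf1 shares were 66.8%, 99.0%, 100% and 2.65%. Pax5 was detected in 0.214% of cluster 2 and 17.0% (12 to 23.1) of cluster 7. Ly6d was found in 51.4% of cluster 2, 93.3% of cluster 7, 19.2% (14.0 to 25.4) of cluster 6, 86.5% of cluster 1 and 88.3% of pDC-like cells, against 7.08% of granulocyte-like cells. Dntt was found in 98.7% of cluster 2, 52.8% of pDC-like cells and 1.45% of cluster 1, against 8.85% of granulocyte-like cells, of which 112 of 113 had suffix 1. Their shares give no background for clusters 1 and 6, which lie mostly in suffix 3, nor for most of cluster 7, with 147 of 195 cells in suffix 2. Without thinning Dntt was found in 76.9% of pDC-like and 51.3% of the deeper granulocyte-like cells. On GRCm38, Ebf1 lies on chromosome 11 at 44617317 to 45008091, Pax5 on chromosome 4 at 44524757 to 44710487, Ly6d on chromosome 15 at 74762056 to 74763620 and Dntt on chromosome 19 at 41029275 to 41059525.

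**Figure D3:**
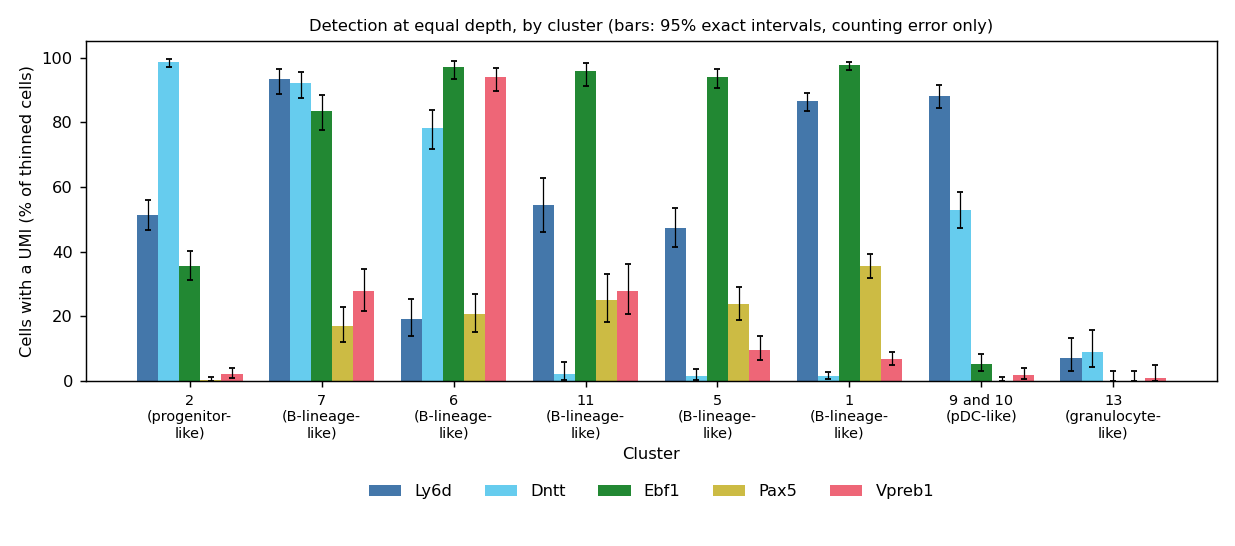
Share of thinned cells with a UMI of Ly6d, Dntt, Ebf1, Pax5 or Vpreb1 (y axis, percent) in each named cluster (x axis), with exact 95% intervals. Ly6d is at 19.2% in cluster 6, against 93.3% in cluster 7 and 86.5% in cluster 1.

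Ly6d, Gfra2 and Bst1 are surface markers that divide or may divide lymphoid progenitors. B-lineage genes were compared between thinned cells with and without their UMIs within each suffix set. Negative cells thus include cells that had a UMI before thinning: in suffix 1, Ly6d was found in 46.8% of thinned and 66.9% of unthinned cells. In suffix 1, Ebf1 was found in 25.2% (22.3 to 28.3) of 842 Ly6d-positive cells and 9.38% (7.61 to 11.4) of 959 Ly6d-negative cells. The pDC gene Siglech was also more frequent in the positive cells, at 22.3% against 5.01%. In suffix 2 the Ebf1 shares were 69.7% (63.8 to 75.1) and 78.0% (62.4 to 89.4), whose intervals overlap, while Cd79b was less frequent in the positive cells, at 44.9% (38.9 to 51.1) against 70.7% (54.5 to 83.9), and Dntt more frequent, at 72.3% (66.5 to 77.6) against 36.6% (22.1 to 53.1). In suffix 3, Vpreb1 was found in 11.1% (8.89 to 13.5) of Ly6d-positive and 44.5% (39.7 to 49.5) of Ly6d-negative cells, Igll1 in 10.8% and 44.0%, and Dntt, the reverse of suffix 2, in 4.04% (2.74 to 5.72) and 29.0% (24.6 to 33.6). Some B-lineage genes were more frequent in the positive cells there, for Cd79b the reverse of suffix 2, with Cd79a in 97.6% (96.2 to 98.6) against 90.3% (87.0 to 93.0), Cd79b in 98.4% against 88.8% and Ebf1 in 98.8% against 94.9%, while the intervals of Pax5, at 32.3% against 25.8%, and Blnk, at 56.3% against 54.5%, overlapped. Gfra2-positive cells of suffix 3 had a Vpreb1 share of 73.9% (58.9 to 85.7) against 20.9% (18.5 to 23.4), and Bst1-positive cells 44.0% (35.9 to 52.3) against 19.8% (17.4 to 22.4). In suffix 2, Vpreb1 was in 53.6% (33.9 to 72.5) of 28 Gfra2-positive cells against 25% (20.04 to 30.5). Intervals of Ebf1, Pax5, Cd79a, Cd79b, Igll1 and Blnk overlapped. For its 14 Bst1-positive cells, Igll1 was at 78.6% (49.2 to 95.3) against 22.1% (17.5 to 27.3). Ebf1 was at 100% (76.8 to 100) against 69.4% (63.8 to 74.6), while intervals of Pax5, Cd79a, Cd79b, Vpreb1 and Blnk overlapped. After thinning, suffix 1 held 9 Gfra2-positive and 5 Bst1-positive cells, while unthinned shares were 2.83% and 1.33% of its cells. Among the 9, Ebf1 was at 77.8% (40.0 to 97.2) against 16.5% (14.8 to 18.3) of negative cells. Cd79a was at 44.4% (13.7 to 78.8) against 3.91% and Cd79b at 55.6% (21.2 to 86.3) against 9.82%, while Pax5, Vpreb1 and Igll1 were in 0 of the 9. The 5 Bst1-positive cells were too few to compare.

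**Figure D4:**
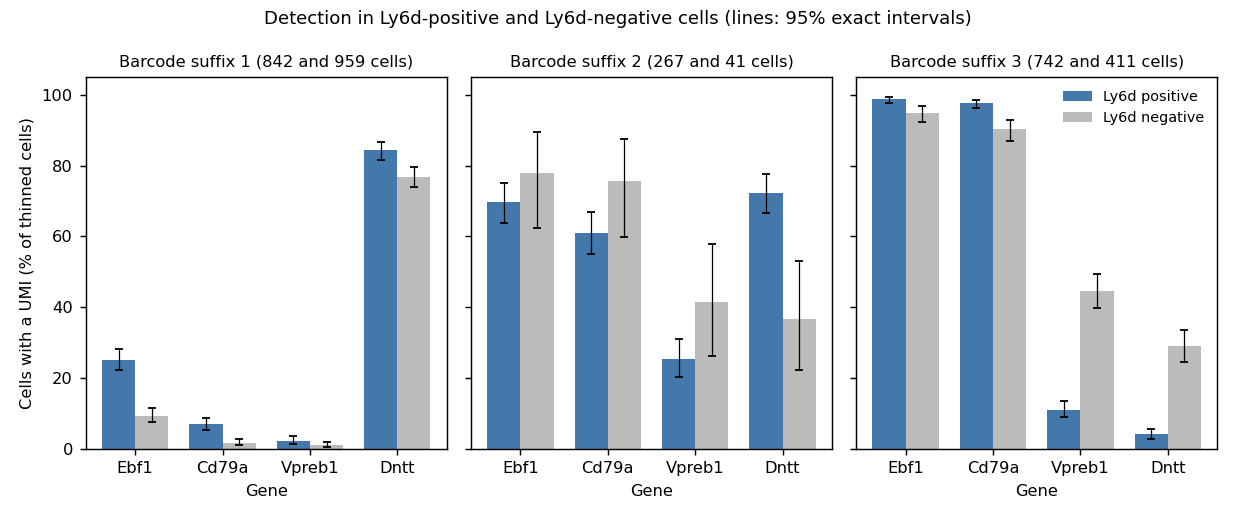
Share of thinned cells with a UMI of Ebf1, Cd79a, Vpreb1 or Dntt (y axis, percent) among Ly6d-positive and Ly6d-negative cells of each barcode suffix set, with exact 95% intervals. In suffix 3, Vpreb1 is at 11.1% in Ly6d-positive and 44.5% in Ly6d-negative cells.

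A UMI of Mki67, Top2a, Cdk1 or Ccnb2, genes of dividing cells, was found in 7.71% (5.46 to 10.5) of thinned cluster 2 cells, 27.3% (21.2 to 34.2) of cluster 7, 47.0% (39.9 to 54.2) of cluster 6, 81.1% of cluster 11, 100% of cluster 5 and 9.0% (6.87 to 11.5) of cluster 1. It was found in 31.5%, 90.2%, 18.9% and 81.8% of the unnamed clusters 3, 4, 8 and 12. Progenitor markers scored 0.46 in cluster 3, 0.09 in cluster 4 and 0.47 in cluster 8, all under the limit for a name. Cells with progenitor transcripts thus lie outside cluster 2 too, and 7.71% is the share of cluster 2 only. In the same way 9.0% leaves out the dividing cells of clusters 5 and 11. The share was 67.0% (61.6 to 72.1) in pDC-like and 62.8% (53.2 to 71.7) in granulocyte-like cells. The pDC-like share leaves out cluster 8, which has pDC markers among its leading genes. Unthinned shares were 27.6%, 47.2%, 55.5%, 89.5%, 100%, 10.4%, 80.9% and 97.3% in the same order of named clusters. Within suffix 2, shares were 27.4% in cluster 7 and 57.7% in cluster 6, with intervals of 20.3 to 35.4 and 36.9 to 76.6, which do not overlap, among 146 and 26 cells. Free RNA was not separated from these shares.

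**Figure D5:**
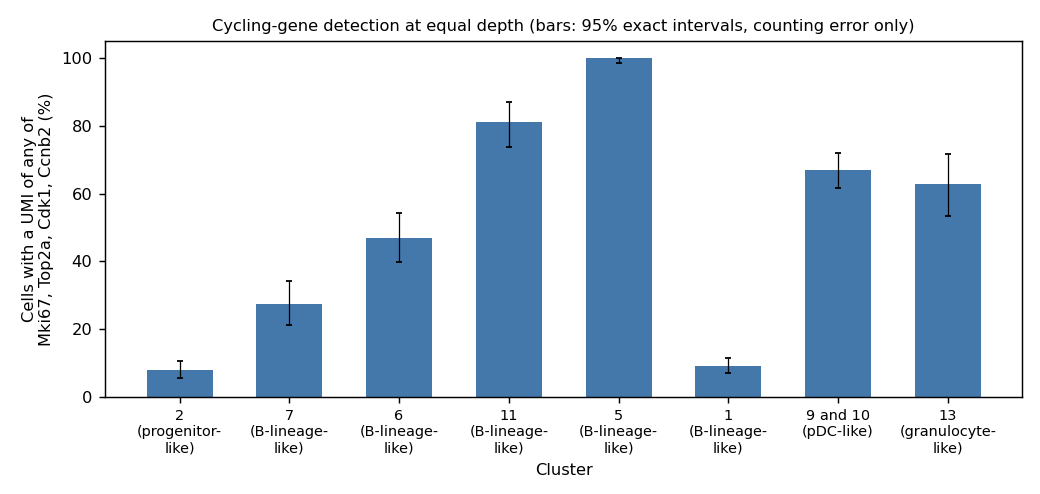
Share of thinned cells with a UMI of any of Mki67, Top2a, Cdk1 and Ccnb2 (y axis, percent) in each named cluster (x axis), with exact 95% intervals. The share is 7.71% in cluster 2 and 9.0% in cluster 1, and 100% in cluster 5.

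Across 2832 genes, cluster 7 was nearest to the progenitor-like cluster 2 (Spearman's correlation 0.911, across genes, which are not replicates), with the unnamed cluster 3 close behind at 0.907. Clusters 6 and 1 were both nearest to the B-lineage-like cluster 11, at 0.870 and 0.807. The pDC-like clusters were nearest to the unnamed cluster 12, whose best-scoring markers were those of monocytes, at 0.903. Clusters 6, 1 and 11 lay mostly in suffix 3, with 172 of 200, 637 of 663 and 135 of 143 cells. Cluster 12, with 119 of 121 cells, and most pDC-like cells had suffix 1. For these pairs likeness of cells cannot be told apart from a shared suffix set. Cluster 7 and cluster 2 lay mostly in different sets.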

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

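Alternatives for the comparisons between clusters, those with other cell filters and the centred similarity were chosen after seeing the data, while the other clusterings, thinning depths and similarity measures had been fixed before. Over all alternatives, values that answer a comparison stayed within their counting interval or range in 137 cases, moved in 93 and reversed in 1; the other values, of single genes, other lists, shares of cells with a UMI and cluster similarity, did so in 1237, 365 and 26. DESeq2 size factors and removal of doublet calls without clustering again reversed no value. No list median reversed with TMM factors, equal weight per cell, totals without mitochondrial and ribosomal protein genes, or leading genes left out. None did under the stricter cell filter, clustered again or not, with no cell filter, or in suffix 1 alone. Cd79a in pDC-like clusters over cluster 2 reversed in suffix 1 alone, at -4.37. Clusters 3 and 4 include dividing cells, which accounts for lower ratios of cell division genes against clusters 2, 3 and 4 together. Fewer counts give fewer cells with a UMI, which accounts for lower shares after thinning; for the other shifts the cause was not tested. With totals without mitochondrial and ribosomal protein genes the median of all genes was -0.12 for clusters 6 and 7 and -0.21 for pDC-like clusters and cluster 2, against -0.02 and 0.03, and values under that setting are to be read relative to it. The comparisons with cluster 2 have no value at resolution 0.5, and clusters of each suffix set alone were used for class shares only. Leaving out non-lymphoid clusters per library and comparing a class between libraries, both intended before, were not run, because cells belong to no known library. Depth limits cluster 1 most, which held 41 of the 45 cells too shallow for thinning.

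Median log2 ratios below are of the cluster or clusters named before over those named after. With TMM factors, medians were for clusters 1 and 6 G2/M-phase -3.28. With equal weight per cell, medians were for clusters 6 and 7 G2/M-phase 1.24, for clusters 1 and 6 G2/M-phase -2.84. With totals without mitochondrial and ribosomal protein genes, medians were for clusters 1 and 6 G2/M-phase -3.31, for pDC-like clusters and cluster 2 multipotent -2.10. With no minimum of summed counts, medians were for clusters 6 and 7 pre-BCR and BCR 0.47, for pDC-like clusters and cluster 2 T, NK and ILC priming 0.065 (reversed, from -0.68). With a minimum of 50 summed counts, medians were for clusters 7 and 2 pre-BCR and BCR 1.35, for clusters 6 and 7 pre-BCR and BCR 0.47, for clusters 1 and 6 G2/M-phase -3.28 and MHC class II 2.26, for pDC-like clusters and cluster 2 myeloid priming 0.048 (reversed, from -0.57). With leading genes and naming markers left out, medians were for clusters 7 and 2 pre-BCR and BCR 0.38 and MHC class II -0.55 (reversed, from 0.90), for clusters 6 and 7 transcription factors -0.49 (reversed, from 0.62) and pre-BCR and BCR -0.34 (reversed, from 0.61), for clusters 1 and 6 MHC class II 0.81, for pDC-like clusters and cluster 2 T, NK and ILC priming 0.085 (reversed, from -0.68). Without leading genes, medians were for clusters 6 and 7 pre-BCR and BCR 0.47. Under the stricter cell filter, medians were for clusters 1 and 6 G2/M-phase -3.27. In suffix 1 alone, medians were for clusters 7 and 2 pre-BCR and BCR 1.29 and multipotent -0.43. In suffix 2 alone, medians were for clusters 7 and 2 pre-BCR and BCR 0.42, V(D)J recombination and end joining -0.34 (reversed, from 0.60), multipotent -1.03 and MHC class II -0.16 (reversed, from 0.90), for clusters 6 and 7 transcription factors -0.075 (reversed, from 0.62) and pre-BCR and BCR 0.028, for clusters 1 and 6 multipotent 0.71 (reversed, from -1.13), G2/M-phase -0.94 and MHC class II 0.83, for pDC-like clusters and cluster 2 multipotent -0.81, myeloid priming 0.47 (reversed, from -0.57), G2/M-phase 1.98, MHC class II 1.07 (reversed, from -0.44) and interferon response 0.67 (reversed, from -1.03). In suffix 3 alone, medians were for clusters 1 and 6 excluded lineages -0.82 (reversed, from 1.53) and G2/M-phase -3.42. Against clusters 2, 3 and 4 together, medians were for clusters 7 and 2 pre-BCR and BCR 3.03, multipotent -0.91, G2/M-phase -0.71 (reversed, from 2.19), ribosome biogenesis and Myc targets -0.037 (reversed, from 0.39) and interferon response 0.10 (reversed, from -0.50), for pDC-like clusters and cluster 2 multipotent -1.34, G2/M-phase 0.97 and MHC class II 0.26 (reversed, from -0.44). At resolution 0.5, medians were for clusters 6 and 7 pre-BCR and BCR 0.82, G2/M-phase 0.96 and MHC class II 0.082 (reversed, from -1.72), for clusters 1 and 6 MHC class II 0.58. At resolution 2.0, medians were for pDC-like clusters and cluster 2 myeloid priming 0.050 (reversed, from -0.57). From 1000 variable genes, medians were for pDC-like clusters and cluster 2 multipotent -1.15, myeloid priming 0.38 (reversed, from -0.57), G2/M-phase 3.66 and glycolysis 0.053 (reversed, from -0.43). With only cell cycle genes out of the features, medians were for clusters 7 and 2 multipotent -0.80, for clusters 6 and 7 pre-BCR and BCR 0.90 and G2/M-phase 2.23, for clusters 1 and 6 excluded lineages -0.62 (reversed, from 1.53), for pDC-like clusters and cluster 2 G2/M-phase 3.14. With list genes among the features, medians were for clusters 7 and 2 multipotent -0.87 and MHC class II -0.11 (reversed, from 0.90), for clusters 6 and 7 pre-BCR and BCR 0.85 and G2/M-phase 1.77, for clusters 1 and 6 excluded lineages -0.66 (reversed, from 1.53) and G2/M-phase -3.50, for pDC-like clusters and cluster 2 G2/M-phase 2.49. Clustered again without doublet calls, medians were for clusters 6 and 7 G2/M-phase 1.75, for clusters 1 and 6 G2/M-phase -3.27, for pDC-like clusters and cluster 2 excluded lineages -0.044 (reversed, from 1.38). With no cell filter, medians were for pDC-like clusters and cluster 2 multipotent -1.35 and G2/M-phase 3.62. Clustered again under the stricter filter, medians were for clusters 6 and 7 G2/M-phase 1.86, for clusters 1 and 6 G2/M-phase -3.28.

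At resolution 0.5, shares were 31.2% progenitor-like. At resolution 2.0, shares were 18.1% progenitor-like and 13.3% pDC-like. From 1000 variable genes, shares were 28.2% progenitor-like and 17.4% pDC-like. With only cell cycle genes out of the features, shares were 33.9% B-lineage-like, 11.4% pDC-like and 1.03% granulocyte-like. With list genes among the features, shares were 33.7% B-lineage-like, 7.71% pDC-like and 1.03% granulocyte-like. Clustered again without doublet calls, shares were 38.2% B-lineage-like, 17.0% progenitor-like and 4.50% granulocyte-like. With no cell filter, shares were 40.4% B-lineage-like, 16.4% progenitor-like and 14.4% pDC-like. Clustered again under the stricter filter, shares were 16.3% progenitor-like, 12% pDC-like and 6.05% granulocyte-like. With suffix sets clustered alone, shares were 26.4% B-lineage-like, 0% progenitor-like, 6.89% pDC-like and 1.94% granulocyte-like. With suffix sets clustered alone on all variable genes, shares were 29.4% B-lineage-like, 0% progenitor-like, 14.7% pDC-like and 1.66% granulocyte-like.

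Without thinning, shares of cells with a cycling-gene UMI were 27.6% in cluster 2, 47.2% in cluster 7, 55.5% in cluster 6, 89.5% in cluster 11, 80.9% in pDC-like clusters and 97.3% in the granulocyte-like cluster, and Ly6d-positive minus Ly6d-negative differences in percentage points were 26.2 for Ebf1 in suffix 1. Thinned to 1000 UMIs, shares of cells with a cycling-gene UMI were 3.64% in cluster 2, 15.9% in cluster 7, 31.0% in cluster 6, 5.73% in cluster 1, 96.3% in cluster 5, 68.5% in cluster 11, 55.4% in pDC-like clusters and 38.1% in the granulocyte-like cluster, and Ly6d-positive minus Ly6d-negative differences in percentage points were 8.98 for Ebf1 in suffix 1 and -24.7 for Vpreb1 in suffix 3.

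The nearest cluster was unchanged with Pearson's correlation and with genes of at least 200 CPM; with the centred measure cluster 1 was nearest to cluster 5 (0.401) in place of cluster 11.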

Other observations

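Of the tests here, those of free RNA and of barcode suffix sets were chosen after the result was seen, and so were the 3 patterns they address. Named classes by barcode suffix are given as values: B-lineage-like clusters held 3.16% of suffix 1 cells, 70.6% of suffix 2 and 100% of suffix 3, and pDC-like clusters held 14.8%, 18.8% and 0%. A group of 12 cells led by Ccl5, Gata3, Id2, Cxcr6 and Rora, also with Cd3d and Cd3g, had innate lymphoid cell markers as its best-scoring set at resolution 0.5, at resolution 2.0, with 1000 variable genes, without doublet calls and with no cell filter, but was not separate in the reported clustering. Igll1 lies on chromosome 16 at 16860671 to 16863985 and Vpreb1 beside it at 16868403 to 16870843.

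Ebf1 was detected in 34.7% (30.4 to 39.3) of the 455 progenitor-like cells of suffix 1, while Pax5 was found in 0.214% of the cluster, and without thinning in 3.85%. The tables argue against free RNA as its source, since the upper bound in granulocyte-like cells of that set was 3.24%, and without thinning 7.63% against 66.2% of progenitor-like cells. They also argue against doublets with B-lineage cells: among the 158 Ebf1-positive cells, 12.7% had a Cd79a or Vpreb3 UMI (upper bound 18.9%), against 78.4% of Ebf1-positive cluster 7 cells. The tables hold more than Ebf1 in cluster 2, with Blnk in 30.2% and Rag1 in 12.8% of its cells, each in 0 of 113 granulocyte-like cells. No biological explanation was tested.

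Ly6d was high in cluster 7, low in cluster 6 and high in cluster 1. A difference between suffix sets as the whole cause is argued against by the log2 ratio of -3.18 (-3.44 to -2.93) for cluster 6 over 7 within suffix 2 and of 4.92 (4.69 to 5.17) for cluster 1 over 6 within suffix 3. Of cluster 6 cells without a cycling-gene UMI, 20% (12.8 to 28.9) had a Ly6d UMI, against 86.7% of such cells in cluster 1. Such cells can still be dividing, since these genes can be missed. Cluster 6 cells with a cycling-gene UMI had Ly6d in 18.3% (11.0 to 27.6). In the dividing clusters 5 and 11 it was found in 47.4% (41.3 to 53.5) and 54.5% (46.0 to 62.9). Lower Ly6d in dividing cells is thus argued against as the whole cause, while a part in it remains open. Clusters carry no order in time, and no biological explanation was tested.

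Dntt was detected in 54.5% (48.3 to 60.6) of the 266 pDC-like cells of suffix 1. Free RNA as a fixed part of each cell's UMIs is argued against by an upper bound of 15.8% in granulocyte-like cells of that set. These were deeper, and thinning dilutes an equal amount of free RNA per droplet more in them, but such an amount is argued against as the whole cause by the unthinned shares, 79.3% (74.0 to 84.0) in pDC-like and 51.8% (upper bound 61.3%) in granulocyte-like cells. Doublets with progenitors would raise the depth, but Dntt-positive pDC-like cells had 1.05 times the median UMIs of the others (0.95 to 1.12, from resampled cells). Free RNA remains open for part of the Dntt-positive cells, and no biological explanation was tested.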
